A study of Mus musculus with 6 samples.

How the data were processed

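RNA sequencing of whole mouse testes at postnatal day 16 compared Hsf5 knockout animals with controls, and the labels list 6 samples, 3 per group. The labels call the controls wild type, while the design text also allows Hsf5 heterozygotes among them, so they were treated as 1 group called control. The labels number the samples but do not say that each came from a separate animal, so p-values measure only the spread between these samples. Libraries were made from total RNA with an NEBNext Ultra RNA kit, per the labels' protocols.

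The submitters' processing notes name cutadapt, Bowtie2, featureCounts, DESeq2 and the mouse build mm39. Their versions, settings and roles, the strand setting and the gene annotation release are not given in the sources used here. The table analysed holds 29333 genes and has value columns for 4 of the samples: control 1, control 2, knockout 1 and knockout 3. Knockout 2 and control 3 were not analysed here. Per the file headers, the authors' deposited table gives for each gene a mean, a log2 fold change of knockout over control with its standard error, a test statistic score, a p-value and an adjusted p-value. The deposited signal per library is a gene's read count divided by 1 size factor per library. This was tested on the values: the share of values in each library that were whole multiples of that library's smallest value, within 1e-06 of a whole number, was 100%. Dividing by that value recovered whole reads, which summed to 18259304 in control 1, 18557898 in control 2, 16824757 in knockout 1 and 16209093 in knockout 3.

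The design fixed before the data were examined named an edgeR test on counts for all samples, with limma if the table held normalized values only. The table held normalized values, so the main test was limma (version 3.58.1, in R 4.3.3) on log2(value + 1) with a mean-variance trend, over 17480 genes with a mean value of at least 10 in the 4 libraries. Each gene's variance was drawn toward the trend over all genes, with 6.3 prior against 2 residual degrees of freedom. The limma p-values therefore rest largely on variance pooled over genes. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and called genes are described as having risen or fallen. Fold changes on the log2(value + 1) scale understate the change of low genes. The edgeR quasi-likelihood test (version 4.0.16, TMM factors) on the recovered reads was added after seeing the data, and called 522 genes higher and 2185 lower of 17773.

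In total 22 gene lists were fixed before the data were examined: cell type markers of spermatogonia, early prophase, pachytene, spermatid, Sertoli, Leydig, myoid, macrophage, endothelial, red blood and epididymal cells, and lists for heat shock factors, chaperones, meiotic division, pachytene transcription regulators, the piRNA pathway, the sex body, Y genes, retrocopies of X-linked genes, the axoneme, p53 and apoptosis, and mitochondrial genes. Lists with at least 5 tested members were compared with all other genes by camera with a preset inter-gene correlation of 0.01, adjusted by the Benjamini-Hochberg method over 20 lists. The camera test was repeated with an estimated correlation, and fry was run beside it. There were 20 genes in more than 1 list, so lists that share genes are not independent results. X-linked and Y-linked genes were compared with autosomal genes by camera and by Fisher's exact test on the called genes.

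Genes named in the text followed a rule fixed before the data were examined. It took the heat shock factors, the 8 called genes with the largest change in each direction among those with a mean of at least 5 CPM (counts scaled to library size) and no overlap between groups, and up to 3 called members of each list with a mean of at least 1 CPM. Where no member was called, the 2 members with the highest mean were taken. Symbols of predicted genes, pseudogenes and unnamed transcripts were left out of the ranking. The rule gave 73 genes, and other genes named were chosen after their values were seen.

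The test was tried on simulated data with the real means and library sizes, over 17197 genes. At most 50 genes were changed at each fold, about as many up as down, and noise was drawn separately for each gene. The real data had many more calls, mostly falls, and broad differences between controls, so the rates here are not those of the real test. It recovered 38% of genes changed 1.5-fold, 58.3% of those changed 2-fold, 85.7% of those changed 4-fold and 100% of those changed 8-fold, with 6 false calls. Folds against a group with no read were computed against a floor of 3 reads over the group and are lower bounds, and folds on 1 to 3 reads carry an exact 95% binomial interval. Such intervals and floors cover counting error only. Values of genes with near-identical copies, among them the Tcp10, Slco6, Cmtm2, globin, Hspa1 and Tuba3 families, are uncertain because the handling of shared reads is not given in the sources used here.

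Alternatives fixed beforehand were DESeq2 (version 1.42.0) and limma-voom on the recovered reads, RLE and upper-quartile factors, library totals alone, scaling to the Sertoli cell list, other filters, thinning to the smallest library, another pseudocount, other thresholds, and leaving out each library. Alternatives chosen after seeing the data were the edgeR test, TMM factors, limma without the mean-variance trend, and removal of each library's trend on GC content. GC content came from the GENCODE M21 transcripts, matched by gene identifier for 97.9% of tested genes. That annotation belongs to another build than mm39, so no coordinates are given, and chromosomes are those of the deposited table.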

Results

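Testes of Hsf5 knockout mice and of controls were profiled by RNA sequencing at postnatal day 16, an age at which the leading wave of germ cells has reached the pachytene stage of meiosis. HSF5 is a heat shock transcription factor family member expressed in spermatocytes. The labels list 3 samples per group, and 2 per group were analysed. Depth lay between 16209093 recovered reads in knockout 3 and 18557898 in control 2. The Spearman correlation over tested genes was 0.987 between the controls and 0.993 between the knockouts. Both pairs differed by more than sampling noise, with a chi-square per degree of freedom of 14.9 and 5.14. Control 1 lay closer to the knockouts than control 2 did, with a correlation to knockout 1 of 0.973 against 0.947.

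Hsf5 itself, on chromosome 11, was checked in every library. Its normalised read count was 2541 in control 1, 3147 in control 2, 1926 in knockout 1 and 1602 in knockout 3. The mean fell from 2844 ± 429 to 1764 ± 229 (SD, n = 2), which left 62.0% of the control level. The log2 fold change was -0.69 (SE 0.12, limma Benjamini-Hochberg adjusted p = 0.00716). The authors' deposited table gives Hsf5 a log2 fold change of -0.69 with a standard error of 0.135 and an adjusted p of 8.18e-06. A gene-level count does not show which part of the transcript remained. HSF5 is expressed in spermatocytes, and the list of pachytene and diplotene markers had a median log2 fold change of -1.72. That list was also higher in control 2 than in control 1 (median log2 difference 0.64), as Hsf5 was. The fall of Hsf5 therefore cannot be told apart from fewer or less advanced spermatocytes, and does not by itself check the knockout. The limma call was lost without control 2 (adjusted p = 0.108), without knockout 3 (adjusted p = 0.072), without a filter on low values (adjusted p = 0.0901) and without the mean-variance trend (adjusted p = 0.145). Of the other heat shock factors tested, Hsf1, the general stress regulator, had a log2 fold change of -0.05, Hsf2 of 0.28 and Hsf4 of 0.08, and none was called by limma over all genes (Benjamini-Hochberg adjusted p = 0.73, 0.102 and 0.934). Adjusted over the list alone, 1 of the 4 members was lower and 1 was higher. This list was too short for a set test.

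The comparison of knockout with control testes asked which genes differ without Hsf5 at this age. The largest falls by the fixed rule, which takes genes with a mean of at least 5 CPM and leaves out predicted and unnamed genes, left few or no reads in the knockout libraries. The only called gene with a lower fitted value than Qrich2 was the predicted gene Gm21269 (-10.80), outside the rule and named after its value was seen. Qrich2, a sperm flagellum protein, fell from 5998 reads in the control libraries to 2 reads in the knockouts, a ratio of 2690 (95% counting interval 745 to 22200). Fbp1, a gluconeogenic enzyme, fell from 2499 ± 1361 to 3.04 ± 0.047 (SD, n = 2). Tcp10c, of the t-complex, and Slco6c1, of the organic anion transporters, had no knockout read and were at least 392-fold and at least 294-fold lower. The ratio was 1300 (233 to 51400) for Cmtm2b, 583 (199 to 2830) for the peroxiredoxin gene Prdx6b and 412 (141 to 2000) for Odf4, an outer dense fibre protein. Rbakdn fell from 1689 ± 948 to 6.54 ± 6.35 (SD, n = 2, limma Benjamini-Hochberg adjusted p = 0.000186). All 8 of these genes kept their call without each library in turn, but each fitted log2 fold change moved by over 1.5 times on the linear scale without a control. It lay between -11.31 for Qrich2 and -8.61 for Rbakdn without control 1, and between -9.71 and -7.39 without control 2. Without knockout 1 and without knockout 3 it also moved for Qrich2 (-9.71 and -11.32), Odf4 (-9.28 and -7.28) and Rbakdn (-8.99 and -7.01).

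Rises were far smaller. By the same rule Tnfrsf12a had the largest, while 10 called genes outside the rule had larger fitted values, up to 2.48 for the predicted gene Gm10175, which was 1.86 without control 1 and 3.11 without control 2 and lost its call without either knockout (limma Benjamini-Hochberg adjusted p = 0.192 and 0.201). Tnfrsf12a, the TWEAK receptor, rose from 235 ± 88.5 to 587 ± 104 (SD, n = 2), a log2 fold change of 1.36. Bbc3, which encodes the proapoptotic protein PUMA, rose by 1.08 on the log2 scale. The other largest rises by the rule were 1.14 for Rpp25, an RNase P subunit, 1.14 for the small noncoding RNA Bc1, 1.12 for the actin acetyltransferase Naa80, 1.08 for Aldh1l1 of folate metabolism, 1.03 for the X-linked gene Tceal6, and 0.99 for Gnas, an imprinted gene that encodes a G protein subunit. All of these passed the limma test, with Benjamini-Hochberg adjusted p between 0.0027 for Aldh1l1 and 0.0145 for Tceal6. Of these, Aldh1l1 alone kept its call without each library in turn. Leaving out any 1 library ended the limma call of Rpp25 (Benjamini-Hochberg adjusted p from 0.0562 to 0.13), Naa80 (0.0585 to 0.146) and Bbc3 (0.0611 to 0.136). Without control 2 the calls of Tnfrsf12a, Bc1, Tceal6 and Gnas were lost (adjusted p = 0.0673, 0.0791, 0.139 and 0.0982), without knockout 1 those of Bc1 and Tceal6 (0.0538 and 0.11), and without knockout 3 those of Tnfrsf12a, Tceal6 and Gnas (0.0828, 0.0955 and 0.101).

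In total 2366 genes fell and 573 rose of 17480 tested (limma, Benjamini-Hochberg adjusted p under 0.05), so 80.5% of calls were falls. At least a 2-fold change was seen in 1175 of the falls and 26 of the rises, and 381 falls reached 8-fold by the fitted fold change. Among the falls, 79 genes had no read in either knockout. Long noncoding RNAs made up 256 of the falls and 21 of the rises, of 1893 tested. The groups did not overlap in 61.7% of tested genes. Random labels would give 33.3% for a single gene, but genes move together, so the excess does not measure an effect of genotype. The authors' deposited table has 2281 genes lower and 458 higher at an adjusted p under 0.05, of which 2163 lower and 433 higher genes were also called here, and no gene was called in opposite directions. The split depended on the scaling: falls were 57.0% of calls with library totals alone and 97.7% when libraries were scaled to Sertoli cell markers. The counts rested on all 4 libraries: 889 falls and 31 rises were called without control 2, 1112 and 74 without knockout 3, 1513 and 74 without knockout 1, and 2096 and 337 without control 1.

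**Figure D1:**
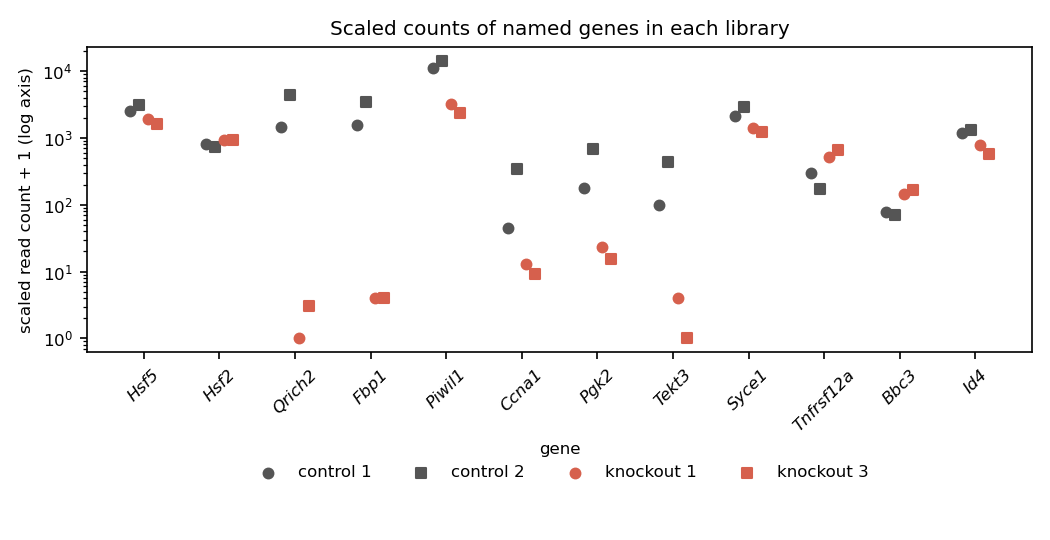
Scaled read counts plus 1 of 12 named genes (log axis) in each of the 4 libraries, with circles and squares marking the libraries within a group. Hsf5 kept 62.0% of the control level in the knockouts, while Qrich2 had 2 knockout reads in all.

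Genes of the axoneme, the microtubule core of cilia and sperm tails, and markers of pachytene and diplotene spermatocytes fell together. In the axoneme list 44 of 48 tested members fell, with a median log2 fold change of -2.46, and 47 were lower adjusted over the list alone. The log2 fold change was -6.29 for the dynein heavy chain Dnah17 and -4.68 for the radial spoke gene Rsph6a, and Tekt3, a tektin, went from 540 to 3 reads, a ratio of 162 (55 to 786). In the pachytene list 34 of 39 members fell, with a median of -1.72, and adjusted over the list alone 36 were lower and 1 was higher. Adam3, a sperm membrane protein (-5.90), Pou5f2 (-5.63) and Spata16 (-4.44) fell most. These calls held without each library, but the values moved: without control 1 and without control 2 the log2 fold change was -7.76 and -5.64 for Tekt3, -5.72 and -3.65 for Rsph6a, -7.20 and -4.60 for Adam3, -6.83 and -4.44 for Pou5f2, and -5.06 and -3.82 for Spata16. For Tekt3 it was -7.70 without knockout 1 and -5.70 without knockout 3. Both lists passed camera (Benjamini-Hochberg adjusted p = 1.83e-20 for the axoneme and 1.24e-13 for the pachytene list), but not with correlation estimated from the data (adjusted p = 0.552 with an estimated correlation for both). The same lists also differed between the controls: the median log2 difference of control 2 over control 1 was 0.84 for the axoneme and 0.64 for the pachytene list.

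The piRNA pathway, which silences transposons in germ cells, fell in 20 of 29 members with a median of -0.67, and adjusted over the list alone 23 were lower and 1 was higher. The log2 fold change was -5.94 for Tdrd6, -2.21 for the Piwi protein gene Piwil1 and -1.63 for Tdrd5. Autosomal retrocopies of X-linked genes fell in 8 of 11 members, also 8 adjusted over the list alone, with a median of -0.71. Among them were Pgk2, a glycolytic enzyme (-4.21), Prps1l1 (-2.95) and Fam50b (-2.77). Round spermatid and acrosome genes were tested for 12 of 40 members, of which 6 fell, also 6 adjusted over the list alone, with a median of -1.04. The acrosomal gene Zpbp2 (-3.64), Dpy19l2 (-3.16) and Fabp9 (-2.78) fell most. At this age the leading wave of germ cells has reached the pachytene stage, so these falls do not show a loss of spermatids. Without control 1 and without control 2 the log2 fold change was -6.63 and -5.25 for Tdrd6, -5.17 and -3.24 for Pgk2, -3.38 and -2.16 for Fam50b, -4.42 and -2.85 for Zpbp2, and -3.76 and -2.56 for Dpy19l2. Leaving out control 2 ended the limma calls of Fam50b, Dpy19l2 and Fabp9 (Benjamini-Hochberg adjusted p = 0.0582, 0.0529 and 0.06). Camera gave a Benjamini-Hochberg adjusted p of 1.67e-07 for the piRNA list, 0.00183 for the retrocopies and 0.0102 for the spermatid list. These calls were lost with correlation estimated (adjusted p = 0.552 with an estimated correlation for the piRNA and retrocopy lists, and adjusted p = 0.553 with an estimated correlation for the spermatid list). The median control 2 over control 1 difference was 0.15, 0.22 and 0.88 in these lists. Piwil1, Tdrd5, Pgk2 and Zpbp2 are also members of the pachytene list, so these falls are not independent of its fall.

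Transcription regulators of pachytene spermatocytes fell in 10 of 23 members with a median of -0.53, and adjusted over the list alone 12 were lower and 1 was higher. Rfx4 (-1.83), Crem (-1.62), which drives postmeiotic genes, and Rfx2 (-1.36), a regulator of ciliary genes, fell most, and the Rfx4 call was lost without control 2 (limma Benjamini-Hochberg adjusted p = 0.0787). Regulators of the meiotic divisions fell in 18 of 42 members, or 22 adjusted over the list alone, with a median of -0.24. Ccna1, the meiotic cyclin A1, fell by 3.49 on the log2 scale, and the log2 fold change was -2.33 for the histone kinase gene Haspin and -1.86 for Pkmyt1, an inhibitory kinase of CDK1. Without control 2 the log2 fold change was -2.03 for Ccna1, whose call was lost (limma Benjamini-Hochberg adjusted p = 0.0801), and -1.53 for Haspin, and without control 1 it was -4.95 and -3.13. The Ccna1 call was also lost without knockout 1 and without knockout 3 (adjusted p = 0.0679 and 0.126), and the Haspin call without knockout 3 (adjusted p = 0.0514). Factors of sex chromosome silencing fell in 5 of 30 members, also 5 adjusted over the list alone, with a median of -0.14. They included Mdc1 (-0.58) and Atr (-0.54), which spread the DNA damage signal over the sex chromosomes, and Rad9b (-0.44). The limma calls of Mdc1 and Atr were lost without control 2 (Benjamini-Hochberg adjusted p = 0.0623 and 0.0682), and that of Rad9b without any 1 library (0.0558 to 0.276). Camera's Benjamini-Hochberg adjusted p was 0.0407 for the regulators, 0.00772 for the divisions and 0.0455 for the silencing factors (adjusted p = 0.552 with an estimated correlation for each). The silencing list lost its call in 13 of 21 settings. The median control 2 over control 1 difference was 0.20, 0.08 and 0.01 in these lists. Ccna1 is also a member of the pachytene list, so the fall of the division list is not independent of that list.

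Heat shock proteins and their co-chaperones moved both ways, with 12 falls and 3 rises among 38 members and a median of -0.17. Adjusted over the list alone, 17 were lower and 4 higher. The falls were largest in the small heat shock protein gene Hspb9 (-6.70), the chaperonin subunit gene Cct6b (-3.18) and Dnajb13 (-2.32), an axonemal protein. The rises were in Hspb8 (0.999), Hspa1b (0.56) and Hspe1 (0.37), chosen after their values were seen. Without control 2 Hspb9 stood at -5.53 with its limma call lost (Benjamini-Hochberg adjusted p = 0.0871). It stood at -7.87 without control 1, -8.19 without knockout 1 and -5.21 without knockout 3, and Cct6b at -3.80 and -2.57 without control 1 and without control 2. All 3 rises lost the call without any 1 library (adjusted p from 0.0516 for Hspe1 to 0.265 for Hspa1b). Camera gave a Benjamini-Hochberg adjusted p of 0.0362 (adjusted p = 0.7 with an estimated correlation).

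Of 46 tested genes of recombination, cohesin and the synaptonemal complex, which are expressed from the start of meiotic prophase, 14 fell, and adjusted over the list alone 14 were lower and 1 was higher. The median log2 fold change was -0.15, and the list was not called by camera (Benjamini-Hochberg adjusted p = 0.0589). The largest falls were in Psmc3ip (-0.94), which aids strand invasion, Syce1 (-0.92), of the synaptonemal complex, and Mlh3 (-0.90), a crossover factor. Spermatogonial markers had 4 rises and 1 fall among 25 members, with a median of 0.21, and adjusted over the list alone 5 were higher and 2 lower. Rhox13 rose by 0.45 and Sohlh1, a regulator of spermatogonial differentiation, by 0.42, while Id4 fell by 0.92 on the log2 scale. Leaving out any 1 library ended the limma calls of Rhox13 (Benjamini-Hochberg adjusted p from 0.0909 to 0.235) and Sohlh1 (0.0545 to 0.228), and leaving out control 2 those of Psmc3ip and Id4 (0.112 and 0.0957). Camera called the spermatogonial list higher (Benjamini-Hochberg adjusted p = 0.0102), a call lost with correlation estimated (adjusted p = 0.581 with an estimated correlation). The median control 2 over control 1 difference in this list was -0.215, about as large as the rise. When libraries were scaled to Sertoli cell markers, which moved the median of all genes to -0.20, the list median was -0.00842. Camera's Benjamini-Hochberg adjusted p was then 0.00917. That is no further support, since such a scaling moves all genes nearly alike and keeps the list's place against other genes.

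Sertoli cell markers rose in 8 of 30 members, or 13 adjusted over the list alone, with a median of 0.23. Defb36 rose by 0.57, Aard by 0.40 and Sox9, a transcription factor of Sertoli cell identity, by 0.38 on the log2 scale. The limma calls of all 3 were lost without control 2 (Benjamini-Hochberg adjusted p = 0.08, 0.187 and 0.193), that of Defb36 also without knockout 1 (0.0792), and that of Sox9 also without control 1 (0.0584) or knockout 3 (0.218). Camera gave a Benjamini-Hochberg adjusted p of 0.000158 (adjusted p = 0.552 with an estimated correlation). Among p53 targets and apoptosis genes, 4 of 35 rose and 2 fell, with a median of 0.13, and 5 were higher and 2 lower adjusted over the list alone. Besides Bbc3, Phlda3 (0.67) and Btg2 (0.63) rose, while Mdm2 (-0.52) and Bcl2l1 (-0.47), which opposes apoptosis, fell and were chosen after their values were seen. Mdm2 is a p53 target as well as an antagonist of p53, so the p53 targets in this list moved both ways. The Bbc3 call was lost without any 1 library (limma Benjamini-Hochberg adjusted p from 0.0611 to 0.136). Without control 2, knockout 1 and knockout 3 in turn the calls of Phlda3 (adjusted p = 0.104, 0.111 and 0.0618) and Btg2 (0.108, 0.111 and 0.062) were lost, and that of Bcl2l1 was lost without control 2 (0.0858) or knockout 3 (0.0803). This list passed camera (Benjamini-Hochberg adjusted p = 0.0184), though not with correlation estimated (adjusted p = 0.552 with an estimated correlation). Under Sertoli scaling its median was -0.080. Camera's adjusted p was then 0.0315, which is no further support, since such a scaling moves all genes nearly alike. Some Leydig cell markers differed widely within groups. Normalised counts in control 1, control 2, knockout 1 and knockout 3 were 284, 1493, 1104 and 332 for Cyp17a1, and 444, 1408, 1112 and 464 for Star. The controls thus differed in more than germ cell genes. Leydig cell markers had 1 rise among 21 members, in Nr5a1 (0.27), the steroidogenic regulator, and none adjusted over the list alone, with a median of -0.19. That rise was lost without any 1 library (limma Benjamini-Hochberg adjusted p from 0.0922 to 0.299).

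No member was called, over all genes or adjusted over the list alone, among 11 myoid, 18 macrophage, 14 endothelial and 7 mitochondrial genes, where limma's log2 fold change was -0.01 for Acta2, 0.23 for Myl9, 0.12 for Lyz2, -0.26 for Mrc1, 0.19 for Cdh5, 0.24 for Eng, -0.14 for mt-Co1 and -0.05 for mt-Cytb. The list medians were 0.06, 0.12, 0.15 and -0.06. Both tested epididymal genes, Wfdc8 (0.15) and Cst8 (-0.17), were not called, over all genes or adjusted over the list alone, and were too few for a set test. Red blood cell genes had 3 rises and 1 fall among 6 members, with a median of 0.65, and 4 were higher and 1 lower adjusted over the list alone. Hbb-bt (0.92), Hba-a1 (0.73) and Hbb-bs (0.57), which encode globins, rose. The limma call was lost without any 1 library for Hbb-bt (Benjamini-Hochberg adjusted p from 0.0989 to 0.173), without control 1, control 2 or knockout 3 for Hba-a1 (0.0858, 0.227 and 0.208), and without control 2 or knockout 3 for Hbb-bs (0.202 and 0.218). Camera called none of these lists, with a Benjamini-Hochberg adjusted p of 0.616 for the myoid, 0.643 for the macrophage, 0.205 for the endothelial, 0.478 for the mitochondrial, 0.0676 for the red cell and 0.419 for the Leydig list.

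**Figure D2:**
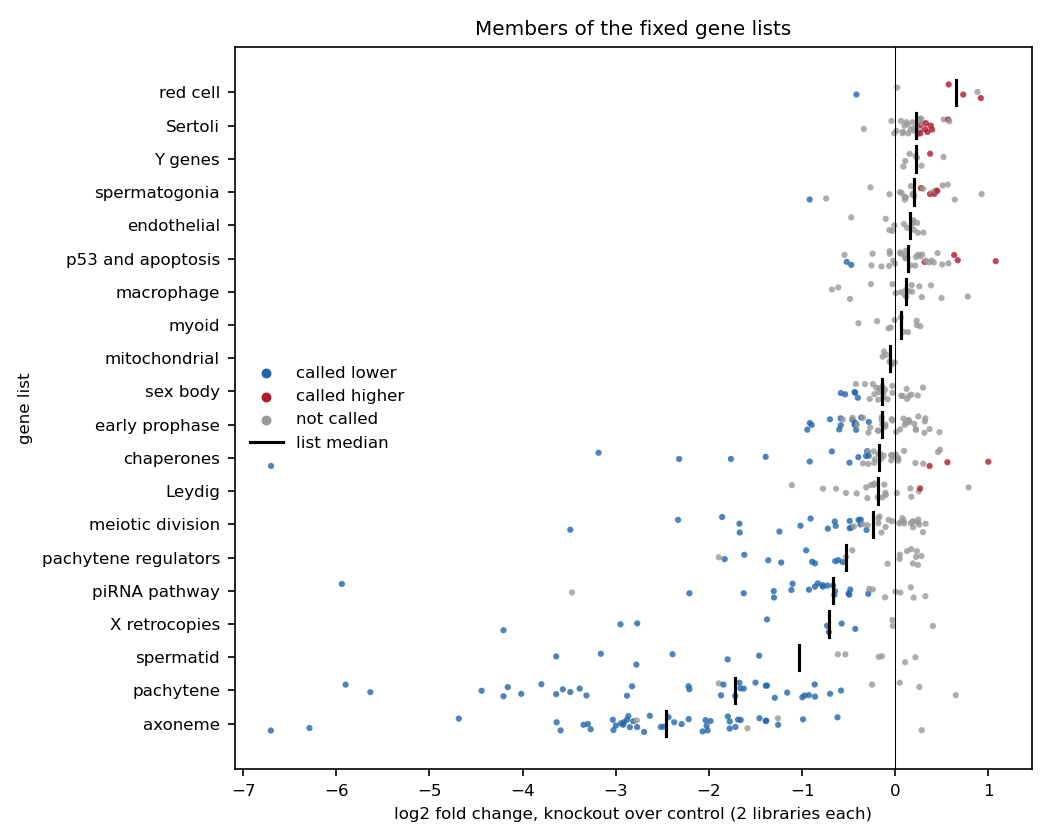
Log2 fold change of knockout over control (horizontal axis) for each tested member of 20 gene lists (vertical axis), with points coloured by call and a black bar at each list's median. The axoneme and pachytene lists have medians of -2.46 and -1.72, and the Sertoli list one of 0.23.

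The sex chromosomes, which are silenced in pachytene spermatocytes, were compared with the autosomes. Of 669 X-linked genes tested, 1 fell and 27 rose, against 2365 falls and 545 rises among 16788 autosomal genes. The fallen gene was the pseudogene Fthl17-ps3, named after its value was seen, whose limma call was lost without control 2, knockout 1 or knockout 3 (Benjamini-Hochberg adjusted p = 0.0585, 0.0721 and 0.083). Falls made up 0.149% of X-linked and 14.1% of autosomal genes (Fisher's exact test, two-sided p = 1.33e-41), and rises 4.04% and 3.25% (p = 0.267). The exact test treats genes as independent, which genes that move together are not. Its p-values in this paragraph are therefore too small and do not measure spread between samples. By the same exact test the comparison of falls lost its call in the settings with few or no falls, which were 0 X-linked and 40 autosomal genes without the mean-variance trend (p = 0.406) and none with pseudocount 0.1 and no filter on low values. Under Sertoli scaling falls made up 2.09% of X-linked and 27.0% of autosomal genes (Fisher's exact test, p = 1.36e-67). Without control 1, control 2, knockout 1 and knockout 3 in turn, 2, 0, 2 and 0 X-linked genes fell and 16, 2, 5 and 5 rose, against 2094, 889, 1511 and 1112 autosomal falls and 321, 29, 69 and 69 autosomal rises, and the largest exact p for falls was 7.9e-16. The comparison of rises also depended on the setting by this exact test: they made up 14.8% of X-linked and 8.40% of autosomal genes with library totals alone (p = 1.08e-07), 14.6% and 8.39% with upper-quartile factors (p = 1.64e-07), 5.13% and 1.96% with the GC trend removed (p = 1.95e-06), and 0.382% and 0.117% without a filter on low values (p = 0.0421). The median log2 fold change was 0.18 on the X chromosome and 0.00 on the autosomes. Camera gave p = 1.09e-09 for the shift, and p = 0.109 with an estimated correlation. The list of Y genes had 1 rise among 8 tested members, Eif2s3y (0.38), a translation factor gene, also 1 adjusted over the list alone. That rise was lost without any 1 library (limma Benjamini-Hochberg adjusted p from 0.0675 to 0.267). The list median was 0.23 (camera Benjamini-Hochberg adjusted p = 0.0362, adjusted p = 0.552 with an estimated correlation), and the list lost its call in 9 of 21 settings.

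**Figure D3:**
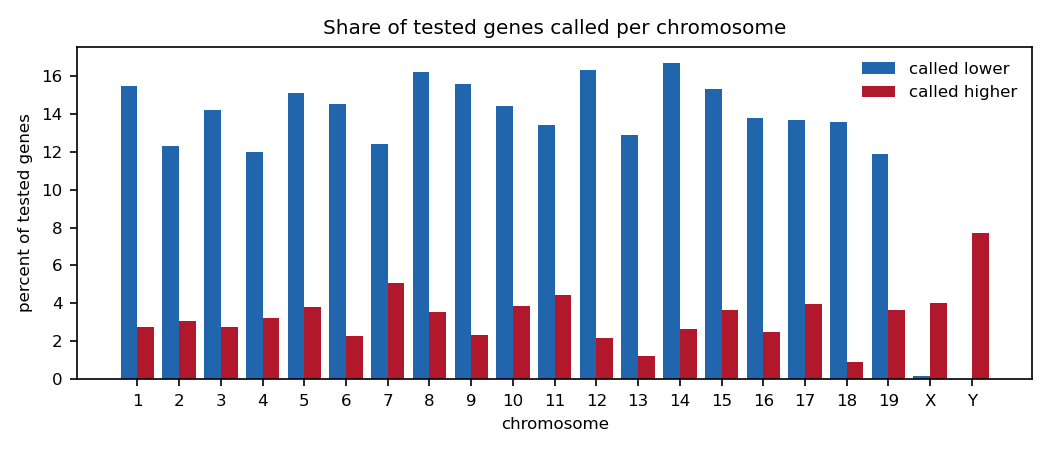
Percent of tested genes called lower and higher (vertical axis, from 0) on each chromosome (horizontal axis), for 2 knockout against 2 control libraries. Falls made up 0.149% of X-linked genes and 14.1% of autosomal genes.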

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

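The edgeR, TMM, no-trend and GC settings were chosen after seeing the data. No paired analysis was possible because the analysed libraries of the groups share 1 replicate number only. Leaving out knockout 2 and control 3 was not run, as they were not analysed here. The cause of the changes below was not tested unless stated. Falls numbered 2293 with DESeq2, 1735 with voom and 2185 with edgeR, against 2366. Rises numbered 1508 with upper-quartile factors, 1511 with library totals alone and 105 with Sertoli scaling, where falls numbered 4547. These settings moved the median of all genes to 0.12, 0.12 and -0.20, and falls to 56.8%, 57.0% and 97.7% of calls. Without a filter on low values 37 rises and 815 falls were called. With pseudocount 0.1 as well, limma called 0 of each (6420 genes at an unadjusted p under 0.05). Without the mean-variance trend it called 0 rises and 40 falls (4283 genes at an unadjusted p under 0.05). Removing the GC trend left 357 rises. By construction, stricter thresholds left fewer: 26 rises and 1175 falls at an absolute log2 fold change of at least 1, and 83 and 1346 at FDR 0.01.

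Hsf5 kept its direction under all settings. Its log2 fold change was -0.69 without a filter, -0.69 with pseudocount 0.1 as well and -0.69 without the trend, with its call lost in each. Leaving out a library, with the lone remaining sample assumed to vary like the other group, gave -0.84 to -0.53 for Hsf5, 31 to 337 rises, 889 to 2096 falls and 1 to 4 lists called higher. With an estimated correlation 0 lists were called lower and 0 higher, and fry in place of camera called 0 lower and 0 higher, against 9 and 4. The smallest fry adjusted p was 0.113, and 14 lists passed its mixed test. The X-linked difference stayed at 0.18 but lost its call with an estimated correlation. The shift of all genes under Sertoli scaling took the spermatogonial median to -0.00842 and the p53 and apoptosis median to -0.080. Camera, which compares a list with other genes, gave a Benjamini-Hochberg adjusted p of 0.00917 and 0.0315. Moving all genes nearly alike keeps that comparison by construction, so it is no further support. The 21 settings for lists include rescalings, which keep a list's place against other genes nearly as it was. They also include limma without the mean-variance trend, which leaves camera unchanged. A list call kept in these settings adds little. Over the 21 settings, the pachytene, axoneme, piRNA, retrocopy, meiotic division and Sertoli lists each lost their call in 2, those with an estimated correlation and with fry. The sex body list lost it in 13, the Y genes in 9, the chaperones in 8, the pachytene regulators in 5, the p53 and apoptosis list in 4, and the spermatogonial and spermatid lists in 3 each. The early prophase list gained a call in 5 and the red cell list in 4. Of 60 named genes called, 31 lost the call without control 2, 20 without knockout 3, 15 without knockout 1 and 11 without control 1, and the fold moved by over 1.5 times in 22, 5, 5 and 22. No named gene reversed under any setting. A 1.5-fold change was recovered for 38% of simulated genes at this depth and sample number. The simulation changed few genes and held no shared difference between controls, so 38% is not the recovery rate of the real test. Small changes stay uncertain with 2 libraries per group.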

Other observations

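The gene groups in this paragraph and the next were chosen after their values were seen. Families of related genes fell almost to nothing. The 3 tested Slco6 transporter genes fell together, with 982, 398 and 70 control reads for Slco6c1, Slco6d1 and Slco6b1 against 0, 0 and 1 knockout reads. The t-complex genes Tcp10a and Tcp10b fell from 2077 to 24 and from 1091 to 6 reads, and Cmtm2a fell from 360 reads to 1. Reads shared between these copies make the split within each family uncertain. Without control 1 and without control 2 the fitted log2 fold change was -9.46 and -8.05 for Slco6c1, -8.19 and -6.68 for Slco6d1, -5.39 and -3.04 for Slco6b1, -6.87 and -5.44 for Tcp10a, -7.95 and -5.94 for Tcp10b, and -7.51 and -6.13 for Cmtm2a. For Tcp10b it was -6.14 without knockout 1 and -7.75 without knockout 3, and the Slco6b1 call was lost without knockout 3 (limma Benjamini-Hochberg adjusted p = 0.0991). Of the 381 genes that fell at least 8-fold, 40 had control values within 0.5 of each other on the log2 scale.

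Ribosomal protein genes rose in 30 of 82 tested cases, and the testis retrocopies Rpl10l and Rpl39l fell (-0.73 and -0.58), with a median of 0.24 (camera p = 1.87e-10, p = 0.338 with an estimated correlation). Under Sertoli scaling the median was 0.03, against -0.20 for all genes, and 8 rose. The Rpl10l call was lost without control 2 (limma Benjamini-Hochberg adjusted p = 0.0713) and the Rpl39l call without control 1, control 2 or knockout 3 (0.0863, 0.353 and 0.296). Among 10 immediate-early genes, 5 rose and none fell, with 0.77 for Jund, 0.70 for Jun, 0.63 for Btg2, 0.60 for Ier2 and 0.51 for Zfp36 on the log2 scale (limma Benjamini-Hochberg adjusted p = 0.0352, 0.0273, 0.0122, 0.0199 and 0.0286). Under Sertoli scaling 1 of them was called. All 5 lost the call without control 2 and without knockout 1 (limma Benjamini-Hochberg adjusted p from 0.108 to 0.21 and from 0.0809 to 0.206), and Jund, Jun, Btg2 and Zfp36 without knockout 3 (0.247, 0.197, 0.062 and 0.116). Without control 1 the calls of Ier2 and Zfp36 were lost (0.0647 and 0.112). The protein-coding genes nearest to Hsf5 in the GENCODE M21 order, Mtmr4 and Rnf43, had log2 fold changes of -0.20 and -0.09 and were not called (limma Benjamini-Hochberg adjusted p = 0.23 and 0.83).

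The regression on the difference between the controls was specified before its result was seen, and the scalings other than TMM were fixed before the data were examined. Their use as tests of the explanations here, and the other tests in this part, were chosen after the results were seen. The pachytene list fell by a median of -1.72, and the early prophase list had a median of -0.15. In these libraries an equal loss of germ cells of every stage as the whole cause is argued against by a difference of -1.57 between the medians (95% bootstrap interval over list members -2.70 to -1.19). List members move together (estimated correlation 0.62 and 0.567), so this interval is too narrow and does not measure spread between samples. A loss at every stage that was larger at late stages stays open. Under Sertoli scaling the early prophase median was -0.36 and the pachytene median -1.93. The pachytene median was at most -1.61 under 6 scalings, the authors' own among them. These scalings placed the median of all genes between -0.199 and 0.125, so none could have brought the pachytene median near 0. The fall thus exceeds the shifts between these scalings, and a larger error of scale was not tested. A candidate explanation is that the knockout testes were less far along a course on which the controls also differ. Of fallen genes, 92.3% were higher in control 2 than in control 1 (interval 91.3 to 93.4), against 48.4% of genes not called. The interval resamples genes that move together, so it does not measure spread between samples. Falls were called from these same controls, so the share is not independent support, and what separates the controls was not tested. Fewer late spermatocytes and lower transcription within them both stay open, untested in whole testes.

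X-linked genes lay above autosomal genes. A GC trend is argued against, since the difference was 0.20 after each library's trend was removed and 0.18 before. Fewer late spermatocytes predicted a smaller gap after regression on the difference between the controls. The gap shrank by 39.6% (95% bootstrap interval over genes 25.8 to 53.2), to 0.11. This interval too resamples genes that move together and does not measure spread between samples. What the difference between the controls reflects was not tested. The controls may include Hsf5 heterozygotes, so stage and genotype cannot be told apart here, and fewer late spermatocytes stay open. Loss of sex chromosome silencing stays open, as the X-linked median differed from the Sertoli list median by -0.046, too little to decide because X-linked genes of other cell types dilute the set.

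Genes that rose were rich in GC, with a median of 55.8% against 49.6% in all tested genes and 47.8% in those that fell. A GC trend between libraries stays open. With each library's trend removed 357 genes were called higher, 285 of them among the 573, and their median GC was above that of all genes tested there by 0.139 percentage points (95% bootstrap interval -0.721 to 0.829). Removing the trend by itself evens out GC, so a technical trend and true rises of GC-rich genes cannot be told apart by this. A shift of scale with no gene rising per cell cannot be told apart from true rises: 105 kept the call under Sertoli scaling, and no external standard sets the scale here.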
